A study of Mus musculus with 6 samples.

How the data were processed

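RNA from 6 samples was measured on 1 Agilent mouse array each, labelled with Cy3: MEF, fibroblasts at 1, 3, 5 and 7 dpi of the Tet3 treatment, and primary embryonic neurons. Per the labels' protocols, fibroblasts received adenoviral supernatants on 2 successive days, and part of the medium was switched to neuronal medium with forskolin on day 3 and again on day 5 after the second infection, so the later arrays differ from MEF in medium as well as in virus. The switches fall on the days of the 3 and 5 dpi arrays, and whether those cells were taken before or after them is not given in the sources used here. Only the array of 7 dpi lies after both switches by its label, so comparisons of 7 dpi with the earlier arrays also involve the medium. Spot intensity values were extracted from the scans with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes, and the deposited intensity columns hold background-corrected signals, per the file headers. The deposited series table holds log2 values that the authors had scaled so that the 75th percentile of each array lies at 0; which software step did so is not given in the sources used here. The column medians of that table were -3.303, -3.234, -3.003, -2.899, -2.864 and -2.503 in the order MEF, 1, 3, 5, 7 dpi and neurons, and its values correlated with those computed here at r of 0.99998 or more.

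From the processed signals, log2 values were computed and the 75th percentile of the array subtracted. That percentile was a signal of 2129.9 for MEF, 1895.2, 2415.8, 1648.1 and 1810.5 for 1 to 7 dpi and 1750.0 for neurons, and no spot was saturated. The spots of a probe were averaged without those marked as outliers, which left 39409 of 39429 probes. Of these, 27222 (69.1%) were given a gene symbol through the accession printed on the array, for 20662 genes, and 12187 probes were not used by name. For the 5469 genes with several probes, the probe with the highest mean signal was used. A difference was taken as measured where both arrays were well above background, as a bound where only 1 was, and as absent otherwise. The scan files put MEF and 1 dpi in 1 scan and the other 4 arrays in another. The mean SD of replicate spots was 0.057 on the log2 scale. The error model gave a median of 0.204 for a difference, over genes well above background on both arrays. Both values cover the array only.

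The 7 planned comparisons set each Tet3 array and neurons against MEF, and the array labelled 7 dpi against neurons and against 1 dpi. Genes at least 2-fold higher or lower were counted. Each of 35 gene lists, fixed before the data were examined, was summarized by the median over its members and by the percentile of that median among 10000 random lists matched on level in 20 bins. The lists were pan-neuronal, proneural and neuronal transcription factors, neural progenitor, synaptic vesicle, glutamate neuron, GABA neuron, voltage-gated channel, axon growth, fibroblast, myofibroblast, mesenchymal, epithelial, cell cycle, p53 target and cell cycle arrest, interferon, inflammatory, antigen presentation, immediate early, DNA methylation, barrier factor, unfolded protein, cholesterol, glycolysis, ribosomal, posterior Hox, imprinted, pluripotency, astrocyte, oligodendrocyte, macrophage, endothelial, skeletal muscle, erythroid, adipocyte and Schwann lists. A percentile describes these arrays and is not a test between groups. Some genes are in more than 1 list, such as Thy1 in the pan-neuronal and fibroblast lists. The genes named are 29 chosen beforehand, the 10 furthest in each direction per comparison, up to 4 members per list with the largest difference, and the 5 in each direction with the largest smallest difference over the 4 times. Left out of the furthest 10 were names that look like predicted genes or clones, and genes with an outlier spot on either array compared. For the 5 in each direction, such a name or an outlier spot on any array left a gene out. Some genes that this rule names are not reported here.

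Alternatives fixed beforehand were normexp background correction with an offset of 50 on median signals (mean signals were not used), quantile normalization, centring on the median, requiring both arrays to be well above background, no filter, the mean over probes, the authors' table, a 4-fold threshold, the mean over members, leaving out members at their bound, and rank correlation. Comparisons within a scan, a filter for brighter genes (log2 level of -1 or more), 6 further gene panels and the tests of explanations were added after the arrays had been described. With the scaling used, the median of all measured genes lay at 0.152, 0.147 and 0.142 for 3, 5 and 7 dpi over MEF and at 0.095 for neurons over MEF; after quantile normalization these were 0.033, 0.014, 0.033 and -0.114, and after median centring the last was -0.144.

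The calling was tested on simulated data, with 7 dpi over MEF as the model and 20662 genes. Among genes well above background in MEF, 57, 54 and 51 were given a difference of 1.5, 2 and 3 on the log2 scale, of which 94.7%, 100% and 98.0% were called in the right direction, and of the unchanged ones 0.133% were called. Recovery was lower for genes not above background in MEF: 9 of 23 made higher and 0 of 15 made lower were called, as were 3 of 3875 unchanged ones. The simulated error was capped at 0.5, which lowered it for 3497 genes, of which 241 were above background in MEF, so errors of dim genes are understated. Of 100 unchanged lists, 6 lay outside the central 95%, and a shifted list lay at the percentile 100. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp, were used.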

Results

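Gene expression was profiled on 6 single-colour oligonucleotide arrays, with 1 array for each group. Mouse embryonic fibroblasts (MEF), the mixed mesenchymal cells grown out of mid-gestation embryos, were the starting cells. Fibroblasts treated with adenoviral supernatants, which the labels describe as neurons induced by Tet3, were profiled at 1, 3, 5 and 7 dpi, and primary embryonic neurons served as a reference. No group was given a virus without Tet3, so infection and Tet3 cannot be told apart on any Tet3 array. There were no replicates, so no test between groups was possible and each difference below describes a pair of arrays. The number of arrays limits the precision of every value. Of 39409 probes, 75.49% were well above background on the MEF array, 72.87% at 1 dpi, 83.28% at 3 dpi, 84.32% at 5 dpi, 77.72% on the array labelled 7 dpi and 86.08% on the neuron array. The arrays were read in 2 scans. MEF and 1 dpi were in the same scan, and 3 dpi, 5 dpi, 7 dpi and neurons were in the other, so scan cannot be told apart from time in any comparison of the later arrays with MEF. Differences are given as folds or on the log2 scale, and "at least" marks a gene that was well above background on only 1 of the arrays compared. The median array error of a difference was 0.20 on the log2 scale by the scanner software's error model, over genes well above background on both arrays. It was larger where an array was near background, such as 1.45 for Insm1 at 7 dpi over MEF. This error does not cover differences between cultures.

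Tet3, the dioxygenase that oxidises 5-methylcytosine and the factor named in the labels, was examined first in every array. The brightest of its 3 probes (NM_183138) was 2.56-fold higher than in MEF at 1 dpi, 3.89-fold higher at 3 dpi and 6.94-fold higher at 5 dpi, but only 1.23-fold higher on the array labelled 7 dpi. A second probe was not well above background in MEF, was at least 24.3-fold higher at 1 dpi, at least 44.1-fold higher at 3 dpi and at least 116-fold higher at 5 dpi, and was again not well above background at 7 dpi. The third probe did not follow them, at 0.73-fold of the MEF signal at 1 dpi and between 1.24-fold and 1.33-fold of it from 3 to 7 dpi. Whether each probe lies inside the introduced sequence is not known here. Tet3 signal therefore went with the labels at 1, 3 and 5 dpi and not at 7 dpi, and the sample is called the array labelled 7 dpi for that reason. In primary neurons the Tet3 probes disagreed: the brightest was at 0.71-fold of MEF and the third at 1.89-fold. The second was not well above background in neurons or in MEF. Of the related enzymes, Tet1 was 4.31-fold higher at 5 dpi and 2.33-fold higher on the array labelled 7 dpi, although its dimmer probe differed less, and Tet2 was within 2-fold of MEF on both.

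**Figure D1:**
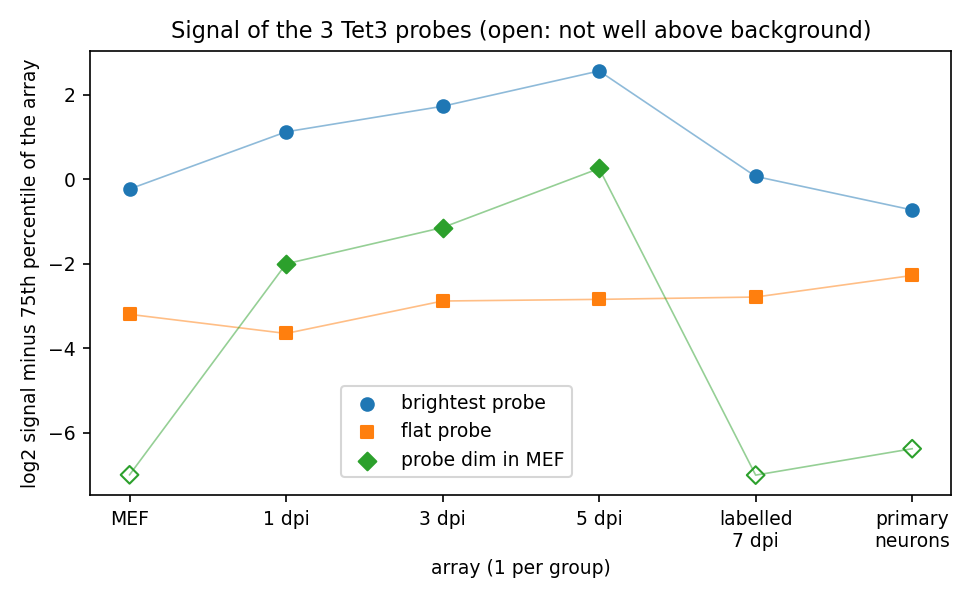
Log2 signal of the 3 Tet3 probes in each of the 6 arrays, relative to the array's 75th percentile, with open symbols for values not well above background. The brightest probe reads -0.23 in MEF, 2.57 at 5 dpi and 0.07 on the array labelled 7 dpi, and the probe that is dim in MEF returns from 0.26 at 5 dpi to -7.00.

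The first comparison asked what differed at 1 dpi, on arrays of the same scan. Lists of interferon-stimulated genes, of p53 target and cell cycle arrest genes, and of contractile genes were higher at 1 dpi than in MEF, and macrophage genes were lower. Oasl1, an antiviral oligoadenylate synthetase-like protein, was 11.4-fold higher and Apol9b was 14.9-fold higher. Perp, a p53 target of cell adhesion and death, was 15.9-fold higher. F13a1, a coagulation factor subunit made by macrophages, was 125-fold lower. At the 2-fold threshold, 903 genes were higher and 1003 lower.

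Of the interferon response genes, 13 of 24 were at least 2-fold higher and 0 lower, with a median log2 difference of 1.04. Oasl1 (3.52), Ifi44 (3.48) and Cxcl10 (3.11) led this list. The list of p53 target and cell cycle arrest genes had a median of 1.07, with 10 of 18 members higher, among them the arrest genes Cdkn2a (2.18) and Cdkn2b (1.73), and 1 lower, the sestrin Sesn1 (-1.98). The myofibroblast and smooth muscle list had a median of 1.21, with 10 of 18 higher, including Actg2 (3.18) and the calponin Cnn1 (2.26). Skeletal muscle genes were also higher, with a median of 1.45 and 9 of 16 members at least 2-fold higher, including the embryonic myosin Myh3 (2.76) and cardiac actin Actc1 (2.43). Immediate early genes were lower, with a median of -0.63, led by Fos (-2.24) and Nr4a2 (-1.35). The pan-neuronal list had a median of 0.35, with 7 of 27 members higher and 2 lower; Tubb3, the neuronal beta tubulin, was 1.27-fold of MEF and Dcx, a microtubule protein of young neurons, was 1.27-fold. The fibroblast and extracellular matrix list had a median of 0.16, and Col1a1, the main fibrillar collagen chain, was 1.12-fold of MEF. Macrophage genes had a median of -2.17, with 13 of 15 lower, led by Mrc1 (-3.72) and Csf1r (-3.65). Each of these medians lay outside the central 95% of 10000 random gene lists of like level, except that of the fibroblast list, at the percentile 96.76.

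Among the genes that differed furthest at 1 dpi, Lrrc10b was 18.8-fold higher, the protease genes Klk8 and Mmp12 were 14.3-fold and 12.3-fold higher, Svop was at least 14.3-fold higher and Ptprb was 12.2-fold higher. In the other direction, Clec10a, a lectin of macrophages, was 42.2-fold lower, Slco2b1 at least 36.4-fold lower, Car2 34.9-fold lower, Ccl8 26.7-fold lower and Upk1a 22.6-fold lower. With only brighter genes kept, a filter chosen after the data were seen, 306 genes were higher and 642 lower. With normexp background correction 524 were higher and 751 lower.

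At 3 dpi, cell cycle, contractile and cholesterol synthesis genes were higher than in MEF, and macrophage genes were lower. The prostaglandin synthase Ptgs2 was 28.0-fold higher. Col2a1, the cartilage collagen, was 30.2-fold higher. Some neuronal genes were higher, among them Tubb3 at 3.15-fold and Map2, a dendritic microtubule protein, at 2.78-fold, while Dcx was at 0.84-fold. By the same threshold, 2948 genes were higher and 1780 lower.

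The cell cycle list had a median of 1.52 with 21 of 30 members higher and 0 lower, led by Cdc20 (2.23), Birc5 (2.02) and the topoisomerase Top2a (1.96). The cholesterol synthesis list had a median of 1.02 with 9 of 18 higher, led by Lss (1.99) and Fdft1 (1.60). Myofibroblast genes had a median of 1.35, with 13 of 18 higher, including Actg2 (4.13) and Cnn1 (3.47). Glycolysis and hypoxia genes had a median of 0.85, led by the oxygen-dependent hydroxylase Egln3 (4.02) and Pfkp (2.12). The interferon list had a median of 1.20 and the p53 target and arrest list 1.08. The pan-neuronal list had a median of 0.96 with 14 of 28 higher and 2 lower, led by Stmn2 (3.24) and Uchl1 (3.18), and a median of 0.60 over the members measured on both arrays. The fibroblast list had a median of -0.30 with 6 of 30 lower and 5 higher; Dcn (-2.71) and Fbln1 (-2.48) were lower and S100a4 (3.66), often used as a fibroblast marker, was higher. The adipocyte list had a median of -0.65 with 4 of 9 lower and 2 higher. Imprinted growth genes had a median of -0.63, led by Cdkn1c (-3.29) and Dlk1 (-2.48). Macrophage genes, whose list median was -4.19, were lower beside all of these groups. Each of these medians over all members lay outside the central 95% of random lists.

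Crct1 at least 60.8-fold, Coch at least 48.4-fold, Mogat2 at 41.4-fold and Cxcl9 at least 37.5-fold were also among the furthest higher at 3 dpi. The furthest lower were the major urinary protein genes Mup17, at least 249-fold, and Mup18, 231-fold, with Reg3g at least 213-fold, Nxpe5 174-fold and Mrc1 149.9-fold lower. The balance of directions depended on the scaling and on dim genes. Of the called genes 62.4% were higher, against 42.7% after quantile normalization, 45.9% with normexp and 40.9% among brighter genes only (785 higher and 1135 lower).

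At 5 dpi, the pan-neuronal, inflammatory and skeletal muscle lists were higher than in MEF, and the macrophage list was lower. Prph, the peripherin intermediate filament found mainly in peripheral neurons, was 226-fold higher, and the neuropeptide Cck was 172-fold higher. Nefh, the heavy neurofilament, was at least 85.4-fold higher, and Insm1, a transcription factor of neuronal and endocrine progenitors, was at least 66.2-fold higher. Ankrd1, a muscle ankyrin repeat protein, was 158-fold higher, and the chemokine Cxcl3 was at least 75.2-fold higher. At the 2-fold threshold, 3287 genes were higher and 1507 lower.

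The pan-neuronal list had a median of 1.26 with 19 of 30 members higher and 0 lower, with Bex1 (5.71) and Nefm (at least 5.66) next after Nefh, and a median of 0.80 over brighter members only. Tubb3 was higher by 2.58 on the log2 scale and Dcx was 3.63-fold of MEF, while Map2 was 1.68-fold of MEF, with a log2 difference of -0.725 from 3 dpi, Syn1 was 0.95-fold and Myt1l was not above background. Neural progenitor markers had a median of 0.97 with 7 of 15 higher and 1 lower, led by Fabp7 (5.09), the Notch ligands Dll1 (3.87) and Dll3 (3.71), and Nes (2.66). Proneural and neuronal transcription factors had a median of 0.96. Neurog2 was 2.55-fold of MEF. The synaptic vesicle list had a median of 0.36, at the percentile 65.28 of random lists. The progenitor and transcription factor medians are given without a percentile. Over the 5166 dimmest of all genes the median difference from MEF was 0.735 at 5 dpi. Inflammatory genes had a median of 1.49 with 12 of 21 higher, led by Cxcl1 (4.82), Ptgs2 (4.70) and Cxcl5 (4.28). Interferon genes had a median of 1.75, p53 target and arrest genes 1.495, cell cycle genes 1.19, myofibroblast genes 1.30 and skeletal muscle genes 1.85, with Actc1 at 4.33. Cholesterol synthesis genes were lower, with a median of -0.57. The fibroblast list had a median of -0.12, with elastin (Eln) at -3.99. The macrophage list, which was lower beside every group named here, had a median of -5.79, and Stab1, a scavenger receptor, was 1165-fold lower.

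Others among the furthest higher at 5 dpi were Kcne1l (142-fold), R3hdml (126-fold), Cox8b (at least 118-fold) and Asb5 (70.7-fold). C1qc was 618-fold, Mrc1 568-fold, C1qa 496-fold and Tbxas1 291-fold lower. Of the called genes 68.6% were higher, against 45.8% after quantile normalization, 58.3% with normexp and 43.2% among brighter genes (781 higher and 1025 lower).

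On the array labelled 7 dpi, a broad set of neuronal genes was higher than in MEF while the main collagen genes were near the MEF level. Nefh was at least 256-fold higher, Stmn3, a neuronal microtubule regulator, at least 251-fold, Insm1 at least 191-fold and the neuronal RNA-binding protein Elavl3 at least 141-fold. Dcx was 34.4-fold, Myt1l 11.7-fold, Tubb3 9.93-fold, Map2 6.52-fold, Rbfox3 3.82-fold and the synaptic vesicle protein Syn1 3.28-fold of MEF. Col1a1 was 1.07-fold, Col1a2 1.00-fold and Fn1 1.24-fold of MEF. Genes of macrophages were lower, with Mrc1 at least 1800.1-fold and C1qc 1062-fold lower. The Tet3 signal, as given above, was near that of MEF on this array, so each difference belongs to the sample and not to a measured Tet3 level. By the 2-fold threshold, 2982 genes were higher and 1197 lower.

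The pan-neuronal list had a median of 3.56, with 21 of 30 members higher and 0 lower, and a median of 2.12 over the members measured on both arrays. Synaptic vesicle and active zone genes had a median of 1.20 with 17 of 26 higher, led by Syt1 (at least 6.29), Cplx1 (at least 5.39) and Syn2 (3.72). Genes of GABA neurons had a median of 1.49 with 14 of 21 higher, led by Gad1 (at least 4.91), and genes of glutamate neurons had a median of 0.95 with 9 of 21 higher, led by Camk2b (4.88) and the vesicular transporter Slc17a6 (2.84). Voltage-gated channel genes had a median of 0.73, at the percentile 86.1, with Kcnc1 at least 5.25 higher. The proneural and neuronal transcription factors had a median of 1.19 with 15 of 27 higher, including Myt1 (at least 3.71) and Lhx3 (3.68), and the progenitor list had a median of 0.95. A panel of peripheral neuron genes, set up after the arrays had been described, had a median of 1.07 at the percentile 97.2, with 8 of 15 higher, and a panel of forebrain neuron genes had a median of 0.72 at the percentile 83.25. The axon growth and guidance list had a median of 0.09. Medians given without a percentile in this paragraph are not placed among random lists here. Over the 5166 dimmest of all genes the median difference from MEF was 0.544 on this array.

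The fibroblast list had a median of 0.31, at the percentile 100, with 4 of 29 members higher, among them Fap (1.68) and Col6a2 (1.62), and 1 lower, Eln (-1.48). The myofibroblast list, higher at the earlier times, had a median of 0.03, and the medians of glycolysis (-0.03) and imprinted growth genes (0.09) were likewise near 0. Single members could still differ from MEF, as did Egln3 (2.87). Interferon genes had a median of 1.23 with 14 of 25 higher, led by Cxcl10 (4.58) and Ifi44 (4.22), inflammatory genes 1.07, p53 target and arrest genes 0.88 and cell cycle genes 0.72. Skeletal muscle genes had a median of 2.53 with 14 of 16 higher, led by Myh3 (5.80) and Actc1 (4.69), and troponin Tnnt2 was 81.9-fold higher. Macrophage genes had a median of -6.60 with 14 of 15 lower, and they were lower beside all the neuronal groups above.

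Other genes furthest higher were Cox8b at least 153-fold, Dusp26 at least 134-fold, the hormone precursor Pomc 133-fold, Cdh22 at least 110.2-fold and the granule protein Vgf 84.0-fold. This ranking holds only genes without an outlier spot. Chgb, which is not in it, had a difference or bound of 9.28 on the log2 scale, larger than that of Nefh. Furthest lower, besides Mrc1 and C1qc, were Stab1 at least 1396-fold, C1qa 732-fold, Trem2 539-fold, Cd300c2 at least 505-fold and Ctss 396-fold. Of the called genes 71.4% were higher, against 48.4% after quantile normalization, 60.2% with normexp and 43.5% among brighter genes (617 higher and 803 lower).

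**Figure D2:**
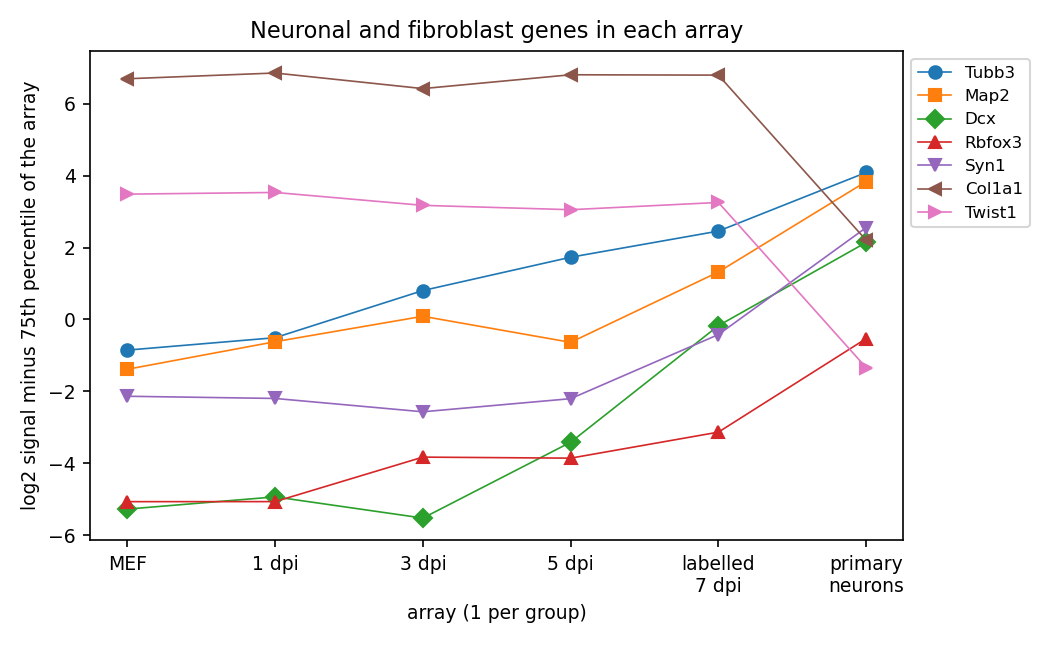
Log2 signal, relative to the array's 75th percentile, of 5 neuronal genes and of Col1a1 and Twist1 in each of the 6 arrays. Tubb3 reads -0.85 in MEF, 2.46 on the array labelled 7 dpi and 4.09 in neurons, while Col1a1 stays between 6.42 and 6.86 on the MEF and Tet3 arrays and reads 2.20 in neurons.

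Primary neurons set the scale for these differences. Stmn3 was at least 1888-fold higher in neurons than in MEF, Syt1 at least 718-fold, Stmn2 633-fold and the progenitor fatty acid binding protein Fabp7 1378-fold. Genes of other brain cells were higher too: Mlc1, an astrocyte membrane protein, at least 3243-fold, the choroid plexus transthyretin Ttr at least 1738-fold, and Foxj1, a factor of ciliated cells, at least 1405-fold. Fibroblast genes were lower, with Agtr2 at least 5548-fold, Aspn at least 1353-fold, Lrrc17 897-fold and Col1a2 94.3-fold lower. At the 2-fold threshold, 5679 genes were higher and 3014 lower.

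The pan-neuronal list had a median of 4.82 with 27 of 30 members higher and 1 lower, the surface protein Thy1, at 2.10-fold lower. GABA neuron genes had a median of 4.55, with Gabra2 at least 8.60 and Sst 8.04 higher, progenitor genes 3.15, channel genes 3.00, synaptic vesicle genes 2.89, glutamate neuron genes 2.64 and neuronal transcription factors 1.88, with Neurod6 (7.96). Astrocyte genes had a median of 2.87 with 9 of 12 higher, led by Gfap (8.97). The fibroblast list had a median of -4.61 with 28 of 29 lower and 1 higher, S100a4, which was 3.63-fold higher. The mesenchymal regulators (-3.15), posterior Hox genes (-3.82), imprinted growth genes (-2.32), antigen presentation genes (-1.56), ribosomal protein genes (-1.05) and interferon genes (-0.92) were lower as lists, and so was the macrophage list (-6.50). Ptbp1, a splicing repressor of neuronal exons, was 2.43-fold lower by its brighter probe, with its other probe at -0.595 on the log2 scale, and its neuronal relative Ptbp2 was 2.62-fold higher. The share of called genes that were higher was 65.3%, against 46.1% after quantile normalization, 54.8% after median centring and 46.1% among brighter genes (2030 and 2374). Bcan (at least 1005-fold) and Scg3 (694-fold) were also among the furthest higher, and Wfdc17 (454-fold) and Pirb (442-fold) among the furthest lower.

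The array labelled 7 dpi and the neuron array were in the same scan and could be compared directly. Fibroblast and posterior patterning genes were higher on the array labelled 7 dpi, and neuronal and glial genes were lower. Agtr2 was at least 5292-fold higher, Aspn at least 1091-fold, Col1a2 93.9-fold and Col1a1 24.1-fold. Mlc1 was at least 2373-fold lower, Ttr at least 1272-fold, the glial potassium channel Kcnj10 at least 918-fold and Gfap 400.3-fold. By the same threshold, 2577 genes were higher and 3632 lower.

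The pan-neuronal list was lower than in neurons, with a median of -1.71 and 23 of 30 members at least 2-fold lower. Mapt (-3.79), Syt1 (-3.20) and Gap43 (-3.10) were lower, and Nefh (3.50) was 1 of 2 members that were higher. Dcx was 4.98-fold, Map2 5.72-fold, Tubb3 3.10-fold and Syn1 7.88-fold lower than in neurons. GABA neuron genes (-2.90), synaptic vesicle genes (-1.97), glutamate neuron genes (-1.94), channel genes (-1.68) and progenitor genes (-1.41) were lower as lists, as were astrocyte genes (-3.79, with 10 of 11 lower), the forebrain panel (-2.40) and the oligodendrocyte list (-1.34). Lhx2 (-6.76) and Sox2 (-7.86 or lower) were far from the neuron level, whereas the peripheral neuron panel was higher by a median of 1.37. The fibroblast list had a median of 4.92 with 28 of 29 higher, led by Pdgfra (8.54) and Twist2 (8.24), the posterior Hox list 4.36, led by Hoxd8 (at least 8.04) and Hoxc6 (7.38), and the interferon list 2.5. Reg3g (at least 1635-fold), Ctla2a (918-fold), Lrrc17 (712-fold) and Saa3 (578-fold) were also among the furthest higher, and Foxj1 (842-fold), Meig1 (452-fold) and Olig1 (at least 406-fold) among the furthest lower. With brighter genes only, 1828 genes were higher and 1795 lower.

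The last planned comparison set the array labelled 7 dpi against 1 dpi. Neuronal and skeletal muscle genes were higher, myofibroblast and macrophage genes were lower, and the fibroblast list was near 0. Nefh was at least 187-fold, Nsg2 146-fold, Insm1 at least 139.8-fold, Stmn3 126-fold and Elavl3 at least 103-fold higher, and Pomc was 87.8-fold higher. Trem2 was 144-fold, C1qc 139.6-fold and Mrc1 at least 136-fold lower. By the 2-fold threshold, 2150 genes were higher and 880 lower.

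The pan-neuronal list had a median of 2.98 with 22 of 30 higher and 0 lower, synaptic vesicle genes 1.30, GABA neuron genes 1.13, inflammatory genes 1.20 and skeletal muscle genes 1.68. The fibroblast list had a median of -0.06, or 0.057 after quantile normalization, myofibroblast genes -1.36 with 11 of 18 lower, led by Cnn1 (-3.00), and macrophage genes -5.00 with 15 of 15 lower. Perp was lower by 2.61 on the log2 scale. These arrays were in different scans. Against 3 dpi, within 1 scan, the pan-neuronal list had a median of 2.01 with 20 of 30 higher and 1 lower, synaptic vesicle genes 0.93, myofibroblast genes -1.58, imprinted growth genes 1.32 and macrophage genes -3.63. Of the called genes 71.0% were higher in the comparison with 1 dpi, against 48.0% after quantile normalization and 54.9% among brighter genes (535 and 439). Against 3 dpi, where no scan difference enters, 2002 genes were higher and 1245 lower. Between 3 and 5 dpi 1502 were higher and 840 lower, and between 5 dpi and the array labelled 7 dpi 1052 were higher and 845 lower.

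**Figure D3:**
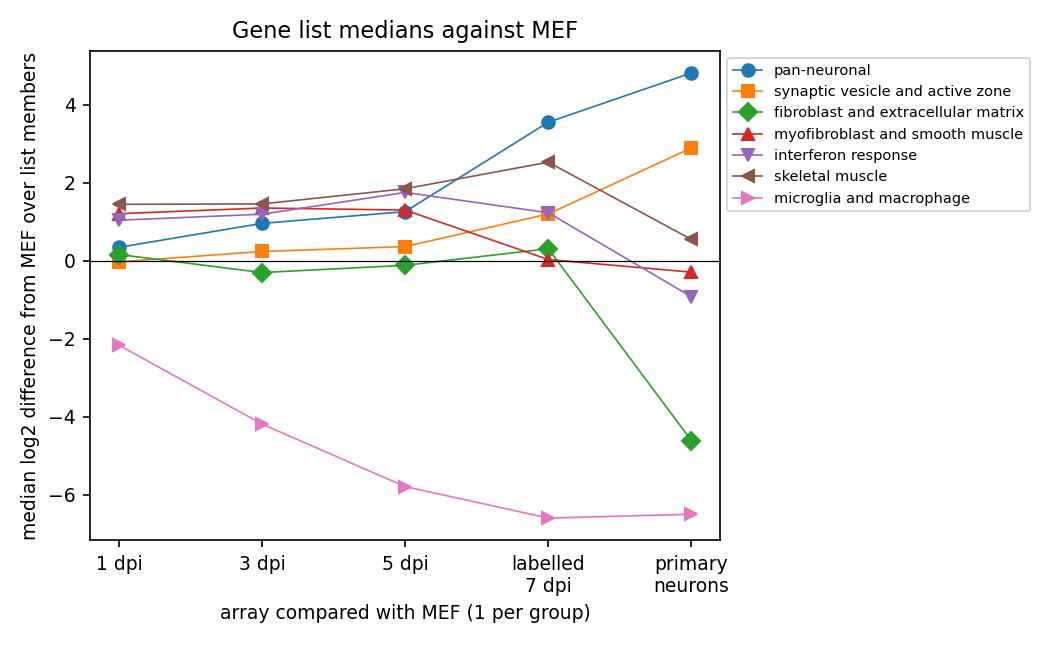
Median log2 difference from MEF over the members of 7 gene lists, at 1, 3, 5 and 7 dpi and in primary neurons, with 1 array per point. The pan-neuronal median goes from 0.35 at 1 dpi to 3.56 on the array labelled 7 dpi, against 4.82 in neurons, and the macrophage median from -2.17 to -6.60.

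Across all 4 Tet3 arrays, 312 genes were at least 2-fold higher and 553 at least 2-fold lower than in MEF, of 15537. The 15537 had a value at every time, no outlier spot on any of the 6 arrays, and no name like a predicted gene or clone. The other counts of 2-fold genes keep such spots and names. The 4 comparisons share the MEF array. In 100 simulations of unchanged arrays with the error of the arrays and a shared MEF array, a mean of 2.4 genes were higher and 2.6 lower at all 4 times, with at most 5 and 7. That covers the error of the arrays only, and a state particular to the single MEF culture would enter all 4 comparisons. The genes with the largest smallest difference were Apol9b, at 3.71 or more on the log2 scale, Ifi44 (3.48), Hoatz (3.42), Ankrd1 (3.29) and Oasl1 (3.29), and in the lower direction F13a1, lower by 6.88 or more, Clec10a, Slco2b1, Ccl8 and Nxpe5.

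Among the remaining lists, the DNA methylation and demethylation genes had medians between 0.06 and 0.29 at the 4 times, with Dnmt3a at -2.60 at 3 dpi. The barrier factors of neuronal conversion had medians between 0.05 and 0.22; Ptbp1 lay between 0.95-fold and 1.04-fold of MEF by its brighter probe, while its other probe was higher by 0.91 on the log2 scale at 3 dpi, and Rest between 0.86-fold and 1.37-fold. The medians on the array labelled 7 dpi were -0.23 for mesenchymal regulators, 0.65 for epithelial markers, -0.30 for antigen presentation, -0.18 for unfolded protein and amino acid stress, 0.14 for cholesterol synthesis, -0.07 for immediate early genes, -0.12 for ribosomal proteins, 0.65 for posterior Hox genes, 0.33 for pluripotency genes, -0.03 for astrocyte genes, 0.01 for the oligodendrocyte lineage, 0.19 for endothelial genes, 1.15 for erythroid genes, 0.88 for adipocyte genes (-1.125 with brighter members only) and 0.38 for Schwann and neural crest genes. Of these, the posterior Hox list was above and the antigen presentation list below the central range of random lists, at the percentiles 99.69 and 2.09. Cdh1, the epithelial cadherin, was not well above background on any array. Actb was between 0.79-fold and 1.1-fold of MEF on the Tet3 arrays, and Gapdh between 0.98-fold and 1.37-fold by its brightest probe, but its other 6 probes were higher by 0.75 to 1.59 on the log2 scale at 3 dpi.

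The differences were also compared across genes, which are not independent replicates. The difference of the array labelled 7 dpi from 1 dpi correlated with the difference of neurons from MEF at r = 0.486 over 15769 genes, with no shared array but with the same scans on both sides. For the difference of 5 dpi from 1 dpi r was 0.485, and for that of 3 dpi from 1 dpi 0.35, so the value was not particular to the last array. Within 1 scan, the difference of the array labelled 7 dpi from 3 dpi correlated with that of neurons from MEF at r = 0.217 over 16087 genes. The difference of 5 dpi from 3 dpi gave 0.213, and that of 7 dpi from 5 dpi gave 0.1. With MEF on both sides, r was 0.605, where unchanged arrays simulated from the error model gave 0.513; the covariance was 1.142, against 0.0239 simulated.

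Control probes without a mouse target, of the ERCC and ETG kinds, were compared in the same way. Over the 10 of 25 that were measurable, the median scaled difference from MEF was 0.16 at 1 dpi, 1.20 at 3 dpi, 1.07 at 5 dpi, 1.01 on the array labelled 7 dpi and 1.32 in neurons. Measurable meant well above background on at least 1 array. Some of these probes were dim in MEF and entered through the later arrays, which can enlarge the medians against MEF. Within the scan of the later time points the medians lay between -0.17 and -0.01. Over the 5166 dimmest genes the median difference from MEF was 0.54 on the array labelled 7 dpi, and over the 5166 brightest -0.03. Genes not above background were kept in these medians. The dimmest genes did not simply follow the scan. Within a scan their median was 0.42 for 1 dpi over MEF, -0.495 for 7 dpi over neurons and 0.115 for 7 over 3 dpi. Between scans it was 0.17 for 7 over 1 dpi.

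**Figure D4:**
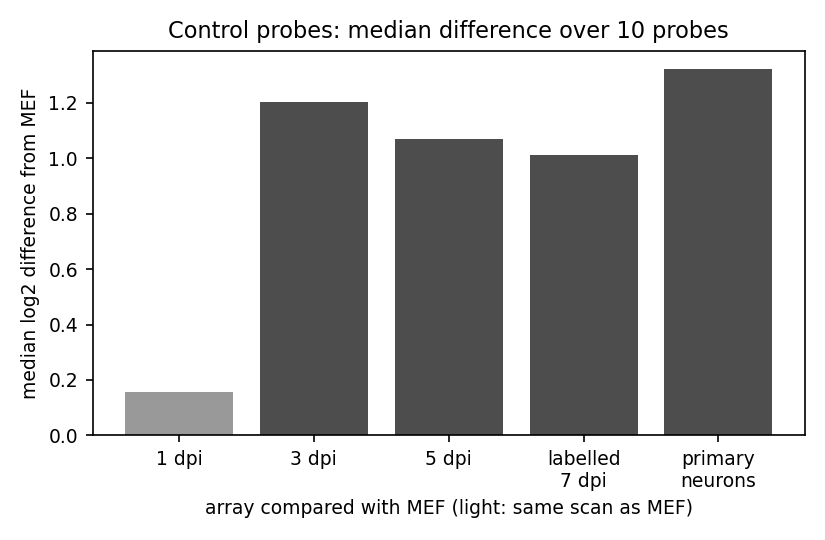
Median log2 difference from MEF, after scaling, of 10 control probes without a mouse target, for each of the other 5 arrays. The array of the same scan as MEF is in light grey. The 1 dpi array lies at 0.16 and the arrays of the other scan between 1.01 and 1.32.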

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

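The tests of a scan difference for the macrophage list and both tests of the Tet3 signal were chosen after the results had been seen, and comparisons within a scan, the second macrophage panel and the peripheral neuron panel were added after the arrays had been described.

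On the array labelled 7 dpi the pan-neuronal median was 3.56 above MEF, or 2.12 over the members measured on both arrays. A level-dependent reading difference was argued against by the percentile 100 among random lists of like level, and a scan difference alone by the percentile 100 against 3 dpi within 1 scan. RNA of primary neurons mixed into the sample would have raised all genes of neurons by a similar share, but the 25th percentile of that share over 843 genes at least 16-fold higher in neurons was 0.074 of the pan-neuronal share, and Gfap, Aqp4, Slc1a2 and Aldoc had a median share of 0.17%. Peripheral neurons carried in the embryo cells stayed open: their panel had a median of 1.075 with a bootstrap SD of 0.56, where 1.778 was needed, and its percentile of 97.2 lay just inside the bound for excluding them, written beforehand, but with an SD of 22.6 over resampled members, of which 21% reached the needed median; this spread was chosen after the values had been seen. Infection with a virus, the neuronal medium, forskolin and time differ from MEF along with Tet3 and could each contribute, which was not tested.

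The macrophage list was lower than in MEF on every Tet3 array. Its percentile of 0.0 among random lists at 1 dpi, within the scan of MEF, argues against a scan difference alone. A second panel of macrophage genes was restricted to the 30 members well above background in MEF. Of these, 100% were at least 2-fold lower at 7 dpi, which goes with fewer macrophages in the Tet3 samples than in the MEF sample. The panel measures transcripts and not cells, so fewer macrophages were not separated from lower expression of these genes within them. If macrophages were fewer, whether they were lost in culture or through the treatment was not tested. Whether they were more numerous in the MEF preparation used was not tested either.

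The Tet3 signal at 7 dpi was back near MEF. A failed spot is argued against because the brightest probe kept 0.107 of its 5 dpi difference while the separate probe that is dim in MEF lay at -7.00, against -6.99 in MEF. The test of a fibroblast culture without virus, in the state of the MEF sample, used 530 genes higher at 1, 3 and 5 dpi. They lost only 0.32 of their difference, and 333 of them (62.8%) were still 2-fold higher. This cannot decide the question, because the genes were chosen against the same MEF array and only genes that rose were examined. The array labelled 7 dpi also shares the scan of 3 and 5 dpi, and its control probes lay 1.01 above MEF. On the same array the pan-neuronal median over MEF was 3.556 and that of the second macrophage panel -6.093. For the genes of these lists, both values argue against a culture in the state of the MEF sample. An expression from the virus that had ended, a culture without virus in another state, and a wrong label remain open.

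The fibroblast median was -0.302 at 3 dpi and 0.309 at 7 dpi against MEF, opposite in sign, a difference that was not tested. The immediate early gene median was -0.632 at 1 dpi and 0.742 at 5 dpi, also untested. The cholesterol synthesis median was 1.022 at 3 dpi and -0.569 at 5 dpi, also untested. The control probes without a mouse target, which no comparison uses, had a median difference of 1.202 at 3 dpi over MEF, and 0.58 after quantile normalization.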

How the results depend on the processing

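The filters for brighter genes and members were chosen after the control probes had been seen.

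No paired analysis was possible because each group is 1 array, and no sample could be left out for the same reason. Signal over background limits dim genes: 72.87% to 86.08% of probes were well above background, and the rest give bounds or no value. Scan and group cannot be told apart for 3, 5 and 7 dpi and neurons against MEF. Of the values of the counts, the pan-neuronal and fibroblast medians and the correlations under the alternatives, 175 kept their size within the spot error or within 1.5 times, and 105 did not. The 105 are given below, for comparisons with MEF unless another array is named; the cause was not tested, apart from the 4-fold threshold and the filters, which keep fewer genes by construction.

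With normexp correction, genes higher numbered 524 (1 dpi), 1270 (3 dpi), 1700 (5 dpi), 1505 (7 dpi) and 1034 (7 over 1 dpi). The pan-neuronal median was 0.62 (3 dpi), 0.97 (5 dpi), 3.14 (7 dpi), 4.24 (neurons), -1.64 (7 dpi over neurons) and 2.70 (7 over 1 dpi). The fibroblast median was -4.44 (neurons) and 4.76 (7 dpi over neurons). With quantile normalization, genes higher numbered 1544 (3 dpi), 1605 (5 dpi), 1407 (7 dpi), 3264 (neurons) and 1121 (7 over 1 dpi). The pan-neuronal median was 0.68 (3 dpi), 0.85 (5 dpi), 3.38 (7 dpi), -2.04 (7 dpi over neurons) and 2.87 (7 over 1 dpi). The fibroblast median was 0.10 (1 dpi), -0.20 (5 dpi), 0.49 (7 dpi), -4.86 (neurons), 5.16 (7 dpi over neurons) and 0.057 (7 over 1 dpi, against -0.059 in the setting used). With median centring, the pan-neuronal median was 0.87 (3 dpi), 1.14 (5 dpi), 3.41 (7 dpi), 4.58 (neurons), -1.62 (7 dpi over neurons) and 2.86 (7 over 1 dpi). The fibroblast median was -0.39 (3 dpi), -0.23 (5 dpi), 0.16 (7 dpi), -4.85 (neurons), 5.01 (7 dpi over neurons) and -0.18 (7 over 1 dpi). The correlation of 7 minus 1 dpi with neurons minus MEF was 0.400 with quantile normalization, and with MEF on both sides 0.509.

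With both arrays required to be well above background, the pan-neuronal median was 0.60 (3 dpi), 1.12 (5 dpi), 2.12 (7 dpi), 4.50 (neurons) and 2.26 (7 over 1 dpi). With members at their bound left out, the pan-neuronal median was 0.60 (3 dpi), 1.12 (5 dpi), 2.12 (7 dpi), 4.50 (neurons) and 2.26 (7 over 1 dpi). With no filter, the pan-neuronal median was 0.41 (1 dpi), 0.86 (3 dpi) and 5.08 (neurons). The fibroblast median was -4.55 (neurons) and 4.84 (7 dpi over neurons). With the mean over probes, the pan-neuronal median was 0.53 (1 dpi), 0.88 (3 dpi) and 3.12 (7 dpi). The fibroblast median was 0.40 (7 dpi), -4.49 (neurons) and 4.85 (7 dpi over neurons).

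At the 4-fold threshold, genes higher numbered 178 (1 dpi), 519 (3 dpi), 731 (5 dpi), 730 (7 dpi), 2524 (neurons), 953 (7 dpi over neurons) and 530 (7 over 1 dpi). Genes lower numbered 223 (1 dpi), 719 (3 dpi), 591 (5 dpi), 536 (7 dpi), 1271 (neurons), 1640 (7 dpi over neurons) and 322 (7 over 1 dpi). With brighter genes only, genes higher numbered 306 (1 dpi), 785 (3 dpi), 781 (5 dpi), 617 (7 dpi), 2030 (neurons) and 535 (7 over 1 dpi). Genes lower numbered 642 (1 dpi), 1135 (3 dpi), 1795 (7 dpi over neurons) and 439 (7 over 1 dpi). With the mean over members in place of the median, the pan-neuronal mean was 0.47 (1 dpi), 0.85 (3 dpi), 1.96 (5 dpi), 3.44 (7 dpi), 4.98 (neurons) and -1.54 (7 dpi over neurons). The fibroblast mean was 0.32 (1 dpi), -0.17 (3 dpi), -0.18 (5 dpi), -4.46 (neurons) and 4.76 (7 dpi over neurons). With brighter members only, the pan-neuronal median was 0.26 (1 dpi), 0.50 (3 dpi), 0.80 (5 dpi), 3.80 (7 dpi), 5.08 (neurons) and -1.63 (7 dpi over neurons).

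A total of 8 other medians had the opposite sign; the cause was not tested. With brighter members only, these were the proneural list at 3 dpi (-0.196), the Schwann list at 5 dpi (-1.045) and the adipocyte list at 7 dpi (-1.125). The Schwann list at 5 dpi was also at -0.117 where both arrays were well above background and where members at their bound were left out. In neurons, the epithelial (-0.440) and skeletal muscle (-0.242) lists had the opposite sign after quantile normalization, and the adipocyte list (0.610) with no filter.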

Other observations

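The neuroendocrine and cartilage panels were chosen after the genes that prompted them had been seen.

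Between 3 dpi and the array labelled 7 dpi, within 1 scan, the genes that differed furthest were of several kinds. Reg3g was at least 2016-fold, Folh1 at least 1175-fold, Mup17 at least 609-fold, Mup18 536-fold, the granin Chgb 498-fold and Reg1 401-fold higher at 7 dpi, with the neuronal genes Nefh, Nsg2 and Insm1 also among the 10 furthest higher, and Col2a1 was 152-fold, Gjb2 at least 87.4-fold and Col10a1 at least 80.4-fold lower. Mup17, Mup18 and Reg3g were at log2 levels of 1.11, 1.44 and 0.885 in MEF and of 2.40, 2.65 and 4.13 at 7 dpi. At 3 dpi Mup18 was at -6.41, and Mup17 and Reg3g were not well above background. Their folds over 3 dpi therefore reflect in large part a low level at 3 dpi. Against 5 dpi, the neuropeptide gene Calca was 57.4-fold, Resp18 at least 46.5-fold and Gad1 at least 33.6-fold higher. All these genes were chosen after their values were seen. A second panel of muscle genes had a median of 1.98 at 7 dpi over MEF, with 14 of 19 members higher.

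The hypothesis that a wider set of neuroendocrine secretory genes was higher at 7 dpi than at 3 dpi was tested on a panel without the genes that prompted it. Its median was 1.90, at the percentile 100 of random lists, with Scg2 at 6.13, Scg5 at 4.96 and Pcsk1 at 4.34, and with Tac1 (-1.66) and Cpe (-1.10) lower. Its member Scg3 had been seen in neurons; without it the median over 20 members was 1.68. The values go with more neuroendocrine transcripts on that array, a hypothesis found and tested on the same arrays. They cannot separate this from a general rise of neuronal genes, because the pan-neuronal list was also higher between these arrays. The members Scg3 and Scg5 were also higher in primary neurons than in MEF, by 9.44 and 6.79. A panel of cartilage genes, run with no prediction, had a median of 0.14 between the same arrays, at the percentile 75.68.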
